A study of Caenorhabditis elegans with 3 samples.

How the data were processed

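Binding of LET-418 was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in wild-type Caenorhabditis elegans (strain N2) at the L3 larval stage, grown at 20 °C as a mixed-sex population. LET-418 is a worm homologue of the chromatin-remodelling ATPase Mi-2 and a subunit of the NuRD and MEC complexes. Per the labels' protocols, frozen ground worms were crosslinked with EGS and then with EGS plus formaldehyde, chromatin was sonicated, and a rabbit polyclonal antibody against LET-418 was used. The labels describe 3 samples, which are 2 ChIP replicates and 1 input DNA library. The input library was not analysed here. The labels do not say whether the 2 ChIP replicates came from separate cultures, so differences between them may be biological or technical.

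Per the submitters' processing notes, reads were aligned with BWA to the ce10 build. Per the file headers, peak positions are on WormBase WS220, and the peak caller is given as MACS. Versions, read filters, the peak threshold and the use of the input are not given in the sources used here. The authors deposited 1 peak list for each ChIP replicate and 1 list for the series, called the combined list below. How the replicates were combined is not given in the sources used here. Each row of the authors' deposited lists holds a chromosome, a 1-based start and end, and a peak score. The scale of this score is not stated. The lowest score was 1.31 in replicate 1, 1.30 in replicate 2 and 1.32 in the combined list, next to the value of 1.30 that −log10 of 0.05 gives, but no p-value was read from the scores. They serve to order peaks within a list, and across lists they enter only correlations and ranks among the same shared sites. The score of the combined list has a ceiling of 9.03, which 246 peaks share. No list overlaps itself. The lists hold no read counts, so the sequencing depth is unknown, and a difference in the number of peaks between lists cannot be separated from a difference in depth or enrichment. Intervals on shares cover counting error only, and peaks are not independent of their neighbours.

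Lists were compared by overlap of at least 1 bp. Each overlap was set against 1000 circular shifts of the replicate 2 list along each chromosome, which keep the number, width and spacing of peaks. The two-sided permutation p is then at least 0.002. Scores were compared across peaks that overlapped exactly 1 peak in each list, with Pearson's r, Spearman's rho and 100000 permutations, for which the smallest p is 1e-05. Peak density was computed over the span from position 1 to the last peak end of any list on each chromosome, 100.2 Mb in all. Bins of about 500 kb gave 95% bootstrap intervals from 2000 resamplings and a permutation test of X against the autosomes. Bins along a chromosome are not replicates and neighbours may be alike, which was not measured, so these p-values may be too small. Each of the 5 autosomes was split into 3 equal parts, and the 2 outer parts were compared with the central part. An exact sign test over 5 autosomes cannot go below p = 0.062. The distance between neighbouring peak midpoints was compared with 1000 random placements of the same number of peaks per chromosome. Share intervals are Wilson intervals at 95%. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.

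The code was tested on simulated lists first. For the overlap of replicates, 8939 simulated peaks with 60.6% truly shared gave 60.6%. The shared peaks were slightly shifted copies, and other peaks that overlapped were removed. This therefore checks the counting only, not how well overlap measures shared binding in clustered lists. For X against autosomes, 8718 simulated peaks with a true ratio of 1.5 gave 1.50 (95% interval 1.33 to 1.67). For the outer against the central parts, the same 8718 peaks with a true ratio of 2 gave 1.98 (1.86 to 2.12). These peaks were placed independently and evenly within each part. The density checks therefore cover the computation of the ratios only, not how well the intervals hold in clustered lists.

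The comparisons, the alternatives and the rule for single peaks were fixed before the data were examined, except where another origin is stated. The alternatives were a reciprocal overlap of 50%, midpoints within 500 bp, the peaks at or above each list's median score, lists of equal length, the list of 1 replicate in place of the combined list, covered bases in place of peak counts, and the outer 20% on each side in place of the 2 outer parts. Bins of 2 Mb and the combined peaks found in both replicates were added after seeing the data. The rule for single peaks took the 25 highest-scoring combined peaks that overlapped a peak in both replicates. Ties at the ceiling were broken by the sum of the ranks of the best overlapping score in each replicate, a step added after seeing the data. Planned comparisons of peaks with promoters, annotation classes, fixed gene lists, repeats and GC content were not run. The gene table at hand is on assembly WBcel235, which is not the build of the peaks, and coordinates of different builds were not mixed. Peaks are therefore given by WS220 position, with no gene names, exons or introns.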

Results

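LET-418 occupancy was mapped by ChIP-seq in L3 larvae of the wild-type strain N2, with 2 ChIP replicates. The replicate 1 list held 16140 peaks covering 5.06 Mb, the replicate 2 list 9817 peaks covering 3.48 Mb, and the combined list of the authors 9187 peaks covering 2.82 Mb. These are 5.06%, 3.47% and 2.81% of the 100.2 Mb spanned. Most peaks were narrow. The median width was 227 bp in replicate 1 (quartiles 177 and 343 bp), 249 bp in replicate 2 (186 and 391 bp) and 229 bp in the combined list (178 and 343 bp), and the narrowest peak was 146 bp in each list. Peaks wider than 1 kb made up 2.44% of replicate 1, 3.99% of replicate 2 and 2.05% of the combined list. Each list held peaks on chromosomes I to V and X. Peak scores are the authors' own, on a scale that is not stated, and the depth behind each list is unknown.

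The first comparison asked how far the 2 replicates marked the same sites. Nearly every replicate 2 site was also found in replicate 1, while many replicate 1 sites were not found in replicate 2. Of the 9817 replicate 2 peaks, 8954 (91.2%, 95% Wilson interval 90.6 to 91.8%) shared at least 1 bp with a replicate 1 peak. Of the 16140 replicate 1 peaks, 8884 (55.0%, 54.3 to 55.8%) shared at least 1 bp with a replicate 2 peak. After circular shifts of the replicate 2 list, the mean shares were 9.93% and 6.17%, and no shift exceeded 16.3% and 10.1% (two-sided permutation p = 0.002 for both, the smallest that 1000 shifts can give). With replicate 1 reduced to its 9817 best-scoring peaks, so that both lists had the same length, the shares were 70.1% of replicate 1 and 72.2% of replicate 2.

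The unshared peaks were weaker and narrower. The 7256 replicate 1 peaks without a partner had a median score of 4.81 and a median width of 185 bp, against 8.95 and 288 bp for the 8884 with one. The 863 replicate 2 peaks without a partner had a median score of 3.19 and a median width of 176 bp, against 5.36 and 262 bp. In replicate 1 the share with a partner was 24.3% (22.3 to 26.4%) in the lowest 10% of scores and 96.3% (95.3 to 97.2%) in the highest 10%. In replicate 2 it was 76.3% (73.5 to 78.8%) in the lowest 10%, and all 982 peaks of the highest 10% had a partner. By chromosome, the share of replicate 1 peaks with a partner lay between 51.7% on I and 58.1% on X, and that of replicate 2 peaks between 89% on I and 92.5% on X.

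**Figure D1:**
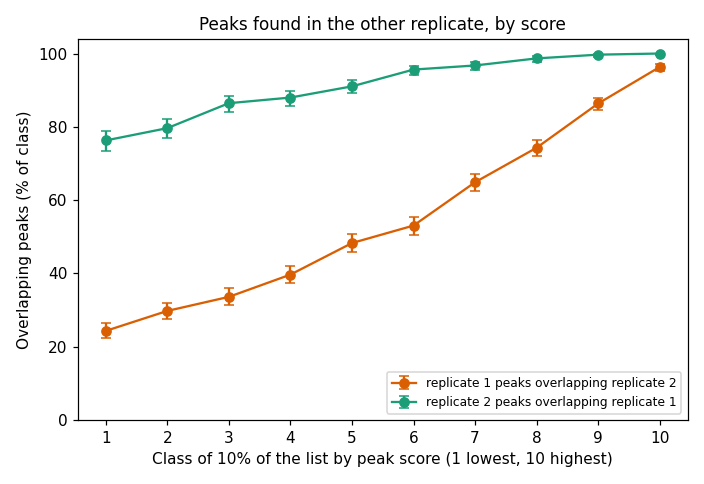
Share of peaks (%) that overlap a peak of the other replicate by at least 1 bp, in 10 equal classes of the list ordered by peak score, for replicate 1 and replicate 2; points are shares and bars 95% Wilson intervals. The share rises from 24.3% to 96.3% in replicate 1 and starts at 76.3% in replicate 2.

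Strong sites in one replicate were strong in the other. Across the 7530 sites where exactly 1 peak of each list overlapped, Spearman's rho of the scores was 0.70 and Pearson's r was 0.78 (permutation p = 1e-05 for each, the smallest that 100000 permutations can give; 2 coefficients were computed, and both adjusted values are also 1e-05). This is a correlation across peaks, which are not independent replicates, and each peak had passed the threshold in both lists.

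**Figure D2:**
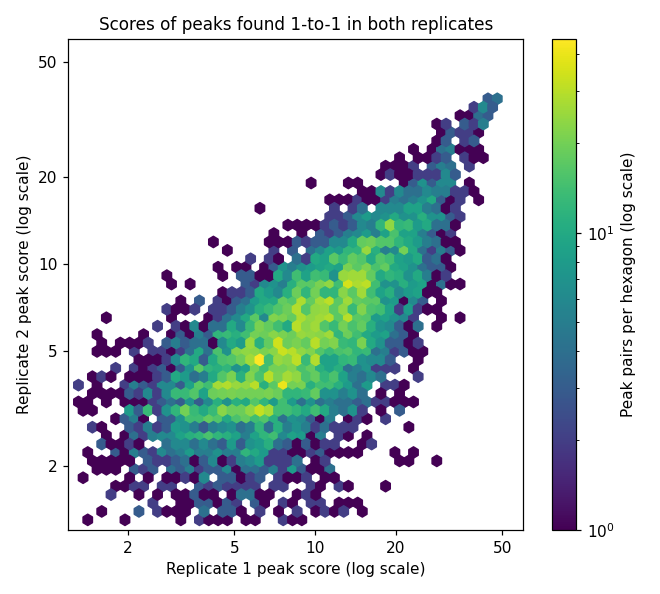
Peak score in replicate 1 against replicate 2 (both log scales, authors' scores) for 7530 sites with 1 peak in each list; colour gives the number of sites per hexagon on a log scale. Sites with high scores in one replicate have high scores in the other, with a Spearman's rho of 0.70.

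The combined list was set against the replicates next. Of its 9187 peaks, 8301 (90.4%, 89.7 to 90.9%) overlapped a peak in both replicates, 815 (8.87%) a peak in replicate 1 alone and 71 (0.773%) a peak in replicate 2 alone, and 0 lacked a partner in both. The median combined score was 4.13 for peaks found in both, 2.97 for those with replicate 1 alone and 2.19 for those with replicate 2 alone. Of the replicate 1 peaks shared with replicate 2, 85.9% overlapped a combined peak, against 10.4% of the unshared ones. The corresponding shares for replicate 2 were 85.5% and 5.33%. When each pair had to cover at least 50% of both peaks, 66.7% of the combined peaks had a partner in both replicates.

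Single sites were taken from the top of the combined list. At the ceiling of the combined score, 9.03, 246 peaks were tied, all of them also present in both replicates, and the 25 with the best replicate scores were taken as named sites. Chromosome III held 8 of these 25, IV held 7, I held 5, II held 4, V held 1 and X held 0. The first of them lay on IV from 4727879 to 4728152 (WS220) and had the highest score of either replicate, 47.9 in replicate 1 and 37.2 in replicate 2. A second site on IV, from 16845423 to 16845723, reached 47.9 and 36.9. On II, the site from 4047884 to 4048187 scored 45.7 and 37.2 in replicates 1 and 2, and that from 3523643 to 3523888 scored 46.4 and 36.9. The IV site from 9196262 to 9196646 scored 47.1 and 36.9. On I, the site from 3037940 to 3038194 scored 47.1 and 35.0, and that from 2639693 to 2639952 scored 45 and 36.4. On III, the peak from 1615831 to 1616877 was 1047 bp wide, the widest of the 25, and scored 43.6 and 37.2, and the peak from 10759029 to 10759429 scored 45 and 33.8. The one site on V ran from 19933107 to 19934078 and scored 43.2 and 30.2. On IV, 3 of the 25 lay close together, starting at 4720558, 4725434 and 4727879. Over all 25, the best overlapping score ranged from 40.0 to 47.9 in replicate 1 and from 30.2 to 37.2 in replicate 2, and the median width was 301 bp.

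Among all 246 peaks at the ceiling, chromosome III held more and X fewer than their shares of all combined peaks, by more than counting error, as they did among the 246 best-scoring peaks of each replicate. The higher share of V and the lower share of I did not hold in both replicates. V was above its share in replicate 1 (20.7%, 16.13 to 26.2%, against 15.3%) but not beyond counting error in replicate 2 (17.5%, 13.2 to 22.7%, against 15.4%), and the interval of I covered its share in each. Chromosome III held 76 of them (30.9%, Wilson interval 25.4 to 36.9%, against 18.3% of all combined peaks), V held 48 (19.5%, 15.04 to 24.9%, against 15.02%), IV held 44 (17.9%, 13.6 to 23.2%, against 14.6%), II held 34 (13.8%, 10.1 to 18.7%, against 15.9%), I held 26 (10.6%, 7.32 to 15.04%, against 16.8%) and X held 18 (7.32%, 4.68 to 11.3%, against 19.4%). On X, 1.01% of peaks (0.641 to 1.59%) were at the ceiling, against 3.08% on the autosomes together, where the share ran from 1.68% on I and 2.33% on II through 3.28% on IV and 3.48% on V to 4.51% on III. This comparison was added after seeing the data.

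**Figure D3:**
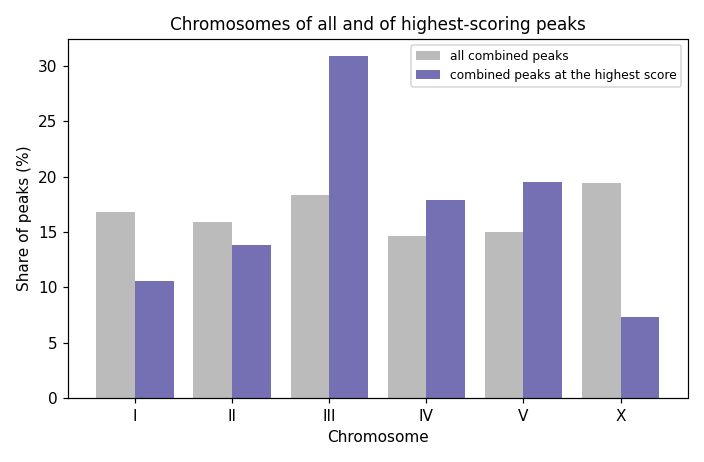
Share (%) of all 9187 combined peaks and of the 246 combined peaks at the highest score on each chromosome; bars are shares with no error. X holds 19.4% of all peaks and 7.32% of the highest-scoring ones, I holds 16.8% and 10.6%, and III holds 18.3% and 30.9%.

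Density by chromosome was compared to ask whether LET-418 sites were distributed differently on X and on the autosomes. Chromosome III had the densest sites, 122 combined peaks per Mb (95% bootstrap interval 102 to 145), and V the sparsest, 66.1 per Mb (55.8 to 76.9). Chromosomes I, II and IV had 103 (90.2 to 116), 95.3 (80.5 to 111) and 76.8 (65.6 to 88.9) per Mb. X had 100.5 per Mb (90.8 to 110) against 89.8 (83.1 to 97.2) on the autosomes together, a ratio of 1.12 (0.990 to 1.27), which did not pass the permutation test over bins (p = 0.199, two-sided). The ratio was 1.09 in the replicate 1 list (permutation p = 0.280) and 1.13 in the replicate 2 list (permutation p = 0.139). In every list III was the densest and V the sparsest. With X as 1 of 6 chromosomes, an exact permutation test over whole chromosomes cannot go below p = 0.167.

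Along the autosomes, no difference between the outer parts and the central part (each autosome cut into 3 equal parts) passed the test in the combined list, but the 2 replicates differed from each other. The ratio of density in the outer parts to that in the centre was 0.989 (95% bootstrap interval 0.864 to 1.14) in the combined list. It was above 1 on III (1.22) and IV (1.10) and below 1 on I (0.953), II (0.908) and V (0.797), with an exact sign test p of 1. In the replicate 1 list the ratio was 1.18 (1.05 to 1.33), and in the replicate 2 list it was 0.853 (0.760 to 0.968). These intervals rest on bins, and over whole autosomes the ratio was above 1 on 4 of 5 in replicate 1 and on 1 of 5 in replicate 2 (exact sign test p = 0.375 for each). The replicate 1 ratio exceeded the replicate 2 ratio by a factor of 1.38 (1.31 to 1.45), resampling the same bins in both lists. Among the combined peaks at or above the median score the ratio was 1.23 (1.05 to 1.44). There it was 1.81 on III and 1.30 on IV, but only 1.03 on I, 1.04 on II and 1.06 on V. All 5 autosomes were above 1 (exact sign test p = 0.062, the smallest possible). The result therefore depended on the score threshold and on the replicate. Single chromosomes were lopsided. The left part of III held 168 peaks per Mb, against 106.5 in its middle and 92.6 in its right part. The left part of IV held 104 per Mb, against 71.8 and 54.6.

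**Figure D4:**
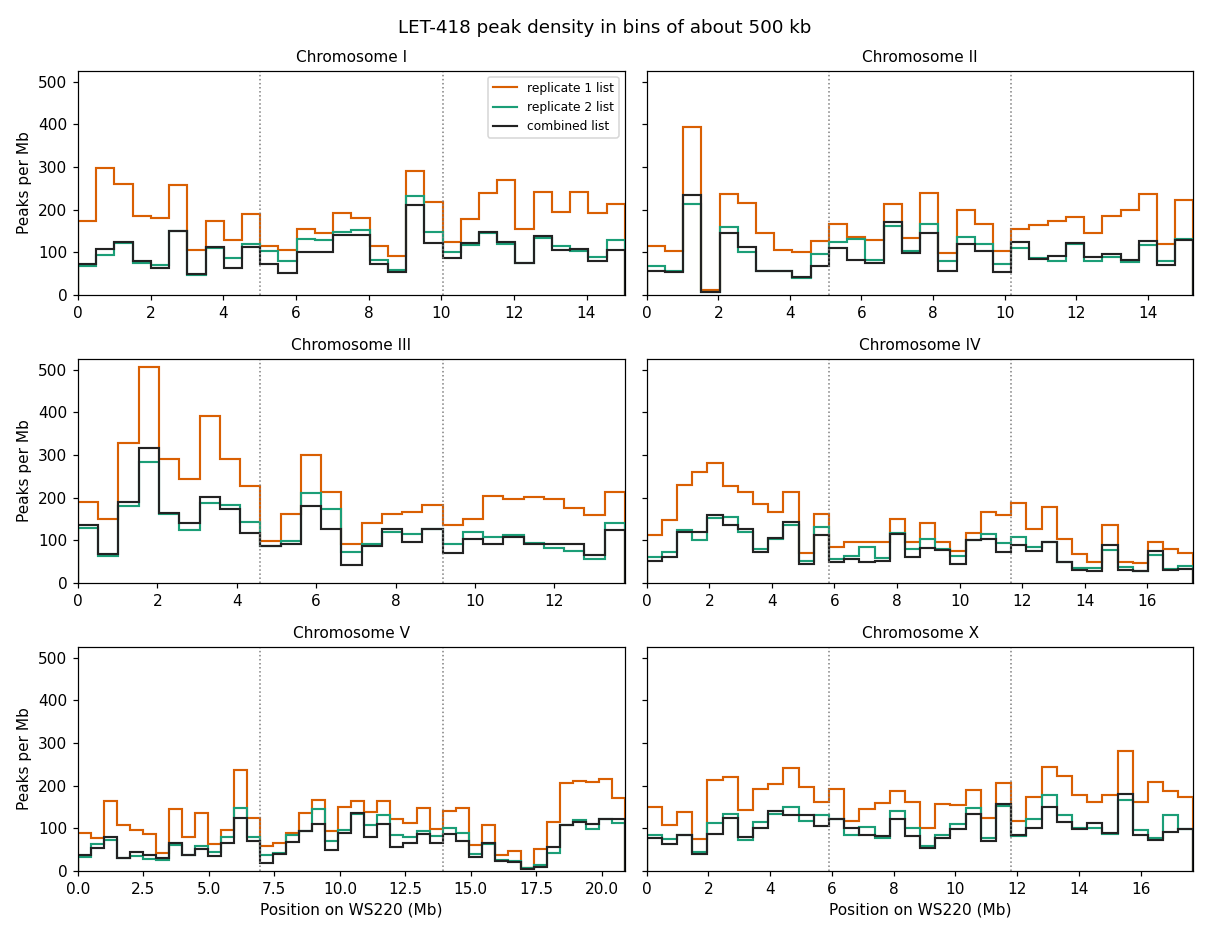
Peaks per Mb along each chromosome (WS220 position in Mb) in bins of about 500 kb for the replicate 1, replicate 2 and combined lists; dotted lines mark the 3 equal parts, and no error is drawn. The left part of III is the densest part in each list, and replicate 1 lies furthest above the other lists in the outer parts.

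Sites were clustered. The median distance between neighbouring combined peak midpoints was 1578 bp, against a mean of 7356 bp and a minimum of 7131 bp over 1000 random placements (two-sided permutation p = 0.002, the smallest possible). The median was 1340 bp in the replicate 1 list and 1582 bp in the replicate 2 list, each with the same p. When combined peaks less than 1 kb apart were joined, 6080 peaks (66.2%) fell into 1804 regions of several peaks and 3107 stood alone. The region with the most peaks lay on II from 6820499 to 6845022 and held 30. The next were on III from 7718354 to 7731879 with 23 peaks, and on X from 12170568 to 12186363 and from 11471108 to 11483197 with 20 each. The widest single peak of either replicate was on V, from 3434573 to 3441163 (6591 bp) in replicate 1 and from 3434581 to 3441149 (6569 bp) in replicate 2, and the combined list held 5 separate peaks there. On III, 1 peak ran from 12612495 to 12616617 in replicate 1 and from 12612506 to 12617115 in replicate 2, where the combined list held 3 peaks under the former and 4 under the latter. These regions were chosen by size after the data were seen.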

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

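The overlap of the replicates stayed above all 1000 shifts under each of the 4 alternatives, with shares of replicate 1 between 46.2% and 70.1% and of replicate 2 between 72.2% and 93.5%. The score correlation stayed positive and past the threshold (rho 0.72 with reciprocal overlap, 0.58 for peaks at or above the median score of their list), and clustering stayed past it in all 4 alternatives (median distances 1340 to 4151 bp, the longest for the combined peaks at or above the median score, which are fewer). The share of combined peaks supported by both replicates fell to 66.7% with a reciprocal overlap of 50%, which is stricter by construction, and was 80.02% among peaks at or above the median score of each list, where fewer replicate peaks are left to overlap. The X to autosome ratio was not past the threshold in any setting. It was 0.996 for peaks at or above the median score, on the other side of 1 (permutation p = 0.969), and 1.09 to 1.13 without 1 replicate. In 10 equal classes of the combined list by score, X held 19.4 to 21.5% of classes 6 to 8. It held 16.9% of class 9 and 12.8% of class 10, against 19.4% of all combined peaks. The lower ratio among better-scoring peaks thus goes with the scarcity of X in the highest classes, the cause of which was not tested. With the combined peaks found in both replicates the X to autosome ratio was 1.15 (permutation p = 0.110), although its bootstrap interval of 1.01 to 1.30 lay above 1. The outer to centre ratio was the least stable result. Judged by bootstrap intervals over bins, it was 0.853 and past the threshold without replicate 1, 1.18 and past it in the other direction without replicate 2, 1.23 and past it for peaks at or above the median score, and 1.02 with the outer 20% on each side, where the interval (0.874 to 1.18) covers 1; beyond the weighing of the replicates' difference under the other observations, the cause was not tested. It was 0.917 (0.802 to 1.06) in peaks found in both replicates. With bins of 2 Mb, the X to autosome ratio was 1.12 (permutation p = 0.368) and the outer to centre ratio 0.989 (0.856 to 1.135). Bins of 2 Mb and the peaks found in both replicates were chosen after seeing the data. Leaving out a replicate means using the list of the other in place of the combined list, since the combined list could not be called again. No paired analysis was possible because there is 1 group with peak lists. The comparisons with promoters, annotation classes, gene lists, repeats and GC content, with their other settings, were not run, for want of an annotation and genome of the same build. Without read counts, the depth behind the difference between 16140 and 9817 peaks is unknown.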

Other observations

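Some stretches of chromosome held few LET-418 sites in all 3 lists, and on II such a stretch adjoined one of the densest. On II, the bin from 1018322 to 1527482 held 234 combined peaks per Mb (201 peaks in replicate 1 and 108 in replicate 2), and the adjoining bin from 1527483 to 2036643 held 5.89 per Mb (6 and 3 peaks). On V, the bin from 16902952 to 17400096 held 2 combined peaks (3 in each replicate). The densest bin was on III, from 1530150 to 2040199, with 162 combined peaks (258 and 145). The longest stretch without a combined peak was 391 kb on II, from 1663800 to 2054949, which held 6 replicate 1 peaks and 1 replicate 2 peak. On V the longest was 338 kb, from 17519416 to 17857145, with 18 and 1. That stretch on V was thus empty in the combined list but not bare in replicate 1. Of 2007 windows of 50 kb, 371 (18.5%) had no combined peak, against 1.51% expected for peaks placed at random within chromosomes. These stretches were picked after the data were seen. Whether reads can be placed uniquely there was not tested.

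The patterns below were noticed in the same lists that the tests use. The test of ranks at shared sites and the test of X peak widths were chosen after related results were seen, and the others before their own results. The first pattern is that the extra sites of replicate 1 lay more often in the outer parts of the chromosomes. It is another view of the difference in outer to centre ratio between the replicates. Positions nearer the ends were not tested. On the autosomes, 77.7% of the replicate 1 peaks without a partner lay in the outer 2 of 3 equal parts, against 63.9% of those with one, a gap of 13.8 percentage points (95% block bootstrap interval 10.8 to 16.44), and the gap was positive on each of I to V and, at 5.53 points, on X. The replicate 2 peaks without a partner went the other way (gap −18.4, −23.1 to −13.5). The gap did not shrink when replicate 1 peaks of like score or like width were compared. It was larger, 21.1 points (17.3 to 24.4), within 5 classes of the score. Within 5 classes of the width it was 16.44 (12.8 to 19.7), an interval that overlaps that of the unmatched gap. These values argue against a tendency of weak or narrow peaks to lie in the outer parts as the reason for the replicate 1 gap. The data are consistent with a signal that is relatively higher over the outer parts as a whole in replicate 1: among the 6026 autosome sites found 1-to-1 in both lists, ranked by score within each list, outer sites stood higher in replicate 1 than in replicate 2 relative to central sites, by a mean of 6.56 percentile points (5.19 to 7.96), with the same sign on all 5 autosomes. As a hypothesis, this may come from the libraries (fragmentation, base composition, background) or from a difference between the worm populations, and peak lists without reads or a same-build genome leave these open.

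The second pattern is the scarcity of X among the strongest sites. Chromosome I was also below its share at the ceiling of the combined list, but at the top of each replicate (13.8% of 246 in replicate 1 and 14.2% in replicate 2) its interval covered its share of all peaks (17.4% and 17.03%). The ceiling of the combined score is not the reason, because the 246 best-scoring peaks of each replicate, whose scores have no such ceiling, held 19 X peaks, 7.72% (Wilson interval 5 to 11.8%), against 19.0% of all replicate 1 peaks and 19.5% of all replicate 2 peaks. Narrower peaks on X do not account for it either. Among autosome combined peaks with widths matched to X, 3.03% (interval 2.30 to 3.87%) were at the ceiling, against 1.01% (0.641 to 1.59%) of X peaks. The median X peak was also no narrower than the median autosome peak, with a difference of 2 bp (−6 to 10) in the combined list. Medians alone say little about the widest peaks. What stays open includes fewer strong LET-418 sites on X, a lower X copy number in the males of a mixed population, and the peak caller's treatment of X, none of which was tested. A lower copy number would act on all X sites, not only on the strongest. No general loss was seen in peak density, with an X to autosome ratio of 1.12 (0.990 to 1.27). The median combined score was slightly lower on X, 3.76 against 3.93 on the autosomes. The highest 10% of scores held 12.8% X peaks in the combined list, 13.95% in replicate 2 and 17.8% in replicate 1, so in replicate 1 the scarcity is largely a matter of the very strongest sites.

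The third pattern is the short distance between neighbouring sites. Broad sites cut into peaks less than 1 kb apart cannot be the whole reason. After such peaks were joined, the median distance between the 4911 regions was 9284 bp, below the lowest of 1000 random placements, 13157 bp (two-sided permutation p = 0.002). Joining imposes a minimum distance, which acts against this result. The median was still proportionally much nearer to random placement than before. The mean over placements was 13858 bp after joining. Before joining, the mean was 7356 bp and the observed median 1578 bp. Broad sites with pieces farther apart than 1 kb are not covered. Placements were even along each chromosome, so the test cannot tell local clustering from uneven density. Whether clusters follow gene density was not tested, and no biological explanation was tested.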
